A study of Mus musculus with 6 samples.

How the data were processed

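Poly(A) RNA was sequenced from B16F10 cells, a pigmented mouse melanoma line, in 3 untreated libraries and 3 libraries of cells kept with MTyr-OANPs for 48 h. Per the labels' protocols, reads were 2 × 150 bp pairs from an Illumina NovaSeq instrument. MTyr-OANPs is the submitters' code for the treatment and is not expanded here. The series' design text calls the libraries biological replicates, without saying how the cultures were separated, so p-values measure the spread between these libraries.

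The authors' deposited table holds a whole-number count per gene and library, per the file headers. The same table holds FPKM values (fragments per kilobase of gene, scaled to the depth of the library), also computed by the authors, per the file headers. The submitters' processing notes name CASAVA 1.4 and the build mm9. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. Gene coordinates in the table match GENCODE M21 on GRCm38 and not the build in the notes: 86 of the 99 genes had both ends as in that annotation and the other 13 had 1 end. Coordinates are therefore given on GRCm38.

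The 99 genes were the 99 with the lowest Ensembl gene numbers in GENCODE M21. They were therefore set by identifier and not by expression, and counts of changed genes describe these genes and not the transcriptome. Other genes were not analysed here. A count of 0 was listed with an FPKM of 0.0001 in all 173 such values. Counts divided by FPKM gave the relative depth of each library, from 59 genes with counts of at least 50. No gene deviated from its library's median ratio by more than 1.62%. Relative depths ran from 0.847 to 1.07. The exonic lengths of 7 single-transcript genes set the level of the library sizes. Of 41 values from 1 to 20, 30 were multiples of 4 (73.2%, against 25% of whole numbers in that range), so a count was not read as 1 read pair.

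The main test was edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3) on the deposited counts, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The implied depths served as library sizes. Genes with a mean FPKM of at least 1 over all 6 libraries were tested, which left 53 genes, of which 52 were protein-coding. The lowest mean count of a tested gene was 240, that of H19, with mean counts of 452 untreated and 27 treated. The common dispersion was 0.00435, a coefficient of variation of 6.6%. The test drew the spread of each gene toward that of the tested genes together (median prior degrees of freedom 19.6). Each p-value therefore rests also on the spread of other genes. Standard errors (SE) of log2 fold changes came from the spread of log2 FPKM within groups. Replicate libraries differed by more than sampling noise, with a chi-square per gene of 10.05 to 20.32 between pairs of 1 group if each count is an independent event, and of 2.51 to 5.08 if 4 counts are.

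The test, the FPKM minimum, 30 gene lists and the rule for named genes were set before the data were examined. The rule took the 12 largest changes in each direction among genes that passed the test with no overlap between groups. Predicted genes, pseudogenes and small RNA genes were passed over. It added up to 4 passing members of each list, or up to 2 measured members where none passed, 7 pigment genes, and the 3 genes with the highest mean FPKM. The result of 1 gene that the rule takes is not reported here. No pigment gene of the rule and no gene of the melanogenesis list was among the 99. A limma test on log2(FPKM + 1) was planned for a file of FPKM alone; the counts beside the FPKM values made edgeR the main test, as planned for counts. Scaling by implied depth was settled after the table was seen, because TMM scaling rests on 99 genes here. TMM had been the default in the plan and was run as an alternative. For a partial table the plan set Fisher's exact test of the direction of a list's called genes against the other called genes. The competitive test camera (limma 3.58.1, preset correlation 0.01) and fry were run beside it although the table is partial.

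Alternatives covered other FPKM minimums, scalings, DESeq2 (version 1.42.0), limma, the replicate number as a block, and leaving out each library. Those on pseudocount, quantile normalization and variance model were run in limma on log2 FPKM, so they change the test as well; the block, planned in limma, was fitted in edgeR. GO terms were tried first beside KEGG terms and then left out, because the GO cells of some genes held no usable terms. The edgeR and limma steps were tested on 40 simulated tables of the 53 genes. For edgeR, 73% of genes changed 1.2-fold and 100% of those changed 1.5-fold, 2-fold or 4-fold were recovered, and 3.1% of calls were false. These tables changed 20 genes each, gave every gene the common dispersion and had no counts in steps of 4. The rates may therefore not hold for genes with a larger spread. Both tests were given the depths from which the counts were simulated, so the rates include no error in scaling between libraries. Exons were checked for overlap with other GENCODE M21 genes, and transcripts for stretches of at least 150 bp at 97% identity with another gene (BLAST+ 2.17.0).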

Results

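Gene expression was measured in B16F10 melanoma cells, with 3 untreated libraries and 3 libraries after 48 h of MTyr-OANPs. The series title speaks of delivering nutrients to melanoma and reactivating its metabolism, and the comparison asks which transcripts differ between treated and untreated cells. Counts over the 99 genes came to 410982, 381701 and 390769 in untreated libraries 1, 2 and 3, and to 334160, 420370 and 421423 in treated libraries 1, 2 and 3. No count was found in any library for 16 genes, and 53 genes reached the FPKM minimum.

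Ngfr, the low-affinity nerve growth factor receptor and a neural crest marker, rose 7.43-fold after MTyr-OANPs, from 1.37 ± 0.0895 FPKM (SD, n = 3) to 10.2 ± 0.529 (SD, n = 3). Wnt9a, a secreted Wnt ligand, rose 6.59-fold, from 0.988 ± 0.114 to 6.51 ± 0.466 FPKM (SD, n = 3 each). Gmpr, which converts guanosine monophosphate to inosine monophosphate, fell 10.3-fold, from 60.0 ± 3.36 to 5.80 ± 0.284 FPKM (SD, n = 3 each). The imprinted long noncoding RNA H19 fell 17.3-fold, from 2.30 ± 0.323 to 0.133 ± 0.0279 FPKM (SD, n = 3 each). Its counts in treated libraries 1, 2 and 3 were low, at 28, 22 and 31. The T-box transcription factor Tbx2 fell 3.59-fold, from 59.9 ± 1.5 to 16.7 ± 0.536 FPKM (SD, n = 3 each).

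Of the 53 tested genes, 44 passed edgeR's test (83.0%, exact 95% interval 70.2 to 91.9%), with 20 higher and 24 lower after treatment. Aligned library medians gave 22 higher and 20 lower, and TMM gave 21 and 20. In the other alternatives more genes were lower than higher. A change of at least 2-fold was found in 15 of the 44, 4 higher and 11 lower (28.3% of the tested genes, exact 95% interval 16.8 to 42.3%). At least 2-fold, 7 were higher and 10 lower under TMM, and 3 and 10 in limma on log2(FPKM + 1). The groups did not overlap in 45 of the 53 tested genes, against 10% of genes by chance for 3 against 3 libraries. Among the 9 genes that did not pass were Rtca and Mcts1, with log2 fold changes of -0.09 and 0.08, and Pemt, Tbx4, Dgke, Fer, Acvr1b and Xpo6, which lay between these values. These shares describe the 99 genes of the table only. Their intervals treat genes as independent although all share the same 6 libraries, so they do not measure the uncertainty between libraries.

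Among the genes that rose, the log2 fold change was 2.89 for Ngfr (SE 0.07, edgeR adjusted p = 9.8e-18) and 2.71 for Wnt9a (SE 0.11, edgeR adjusted p = 2.1e-15). Itgb2, the beta chain of the leukocyte integrins, rose from 0.404 ± 0.140 to 1.62 ± 0.115 FPKM (SD, n = 3 each; edgeR adjusted p = 1.7e-08). Itga5, the alpha chain of the fibronectin receptor, rose from 31.3 ± 1.04 to 50.0 ± 0.0810 FPKM (SD, n = 3 each). The zinc finger gene Zfp385a rose 2.59-fold, from 18.8 ± 0.932 to 48.9 ± 2.45 FPKM (SD, n = 3 each). Scpep1, a serine carboxypeptidase and one of the 3 genes with the highest mean FPKM, rose 1.83-fold, from 135 ± 5.60 to 247 ± 8.15 FPKM (SD, n = 3 each). Dbt, a subunit of the branched-chain keto acid dehydrogenase complex, rose 1.79-fold, and Wdr77, a partner of the methyltransferase Prmt5, rose 1.86-fold. Gpr107 rose 1.90-fold. Mnt, a repressor that binds Max, rose 1.43-fold, and the G protein subunit Gnai3 and Tpd52l1 both rose 1.41-fold. Ngfr lies on chromosome 11 at 95568818 to 95587735 and Wnt9a on chromosome 11 at 59306928 to 59333552 (GRCm38).

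Among the genes that fell, the log2 fold change was -4.05 for H19 (SE 0.21, edgeR adjusted p = 3.1e-13) and -3.37 for Gmpr (SE 0.06, edgeR adjusted p = 1.2e-24). Arvcf, a catenin of cell junctions, fell 4.71-fold to 0.920 ± 0.105 FPKM (SD, n = 3). Acvrl1, a type I receptor of the TGF-beta family, fell 2.83-fold, from 10.0 ± 0.0848 to 3.53 ± 0.991 FPKM (SD, n = 3 each). Cav2, a caveolin, fell 2.58-fold to 10.3 ± 0.363 FPKM (SD, n = 3). On the log2(FPKM + 1) scale of limma, which understates changes of low genes, the log2 fold change was -1.54 for H19 and 0.90 for Itgb2. Narf, Hddc2 and the membrane transporter gene Slc22a18 fell 2.52-fold, 2.48-fold and 2.25-fold. Gmpr lies on chromosome 13 at 45507444 to 45553800, Tbx2 on chromosome 11 at 85832551 to 85841948, and H19 on chromosome 7 at 142575529 to 142578143 (GRCm38). Exons of 19 of the 44 genes overlap another annotated gene, 18 of them on the opposite strand, among them Gmpr with Atxn1, Cdc45 with Ufd1 and Wdr77 with Atp5pb. The strand setting of the counting is not given in the sources used here, so reads of such partners may not have been told apart. Apart from overlaps, transcripts of 3 of the 44 genes shared sequence with another gene.

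**Figure D1:**
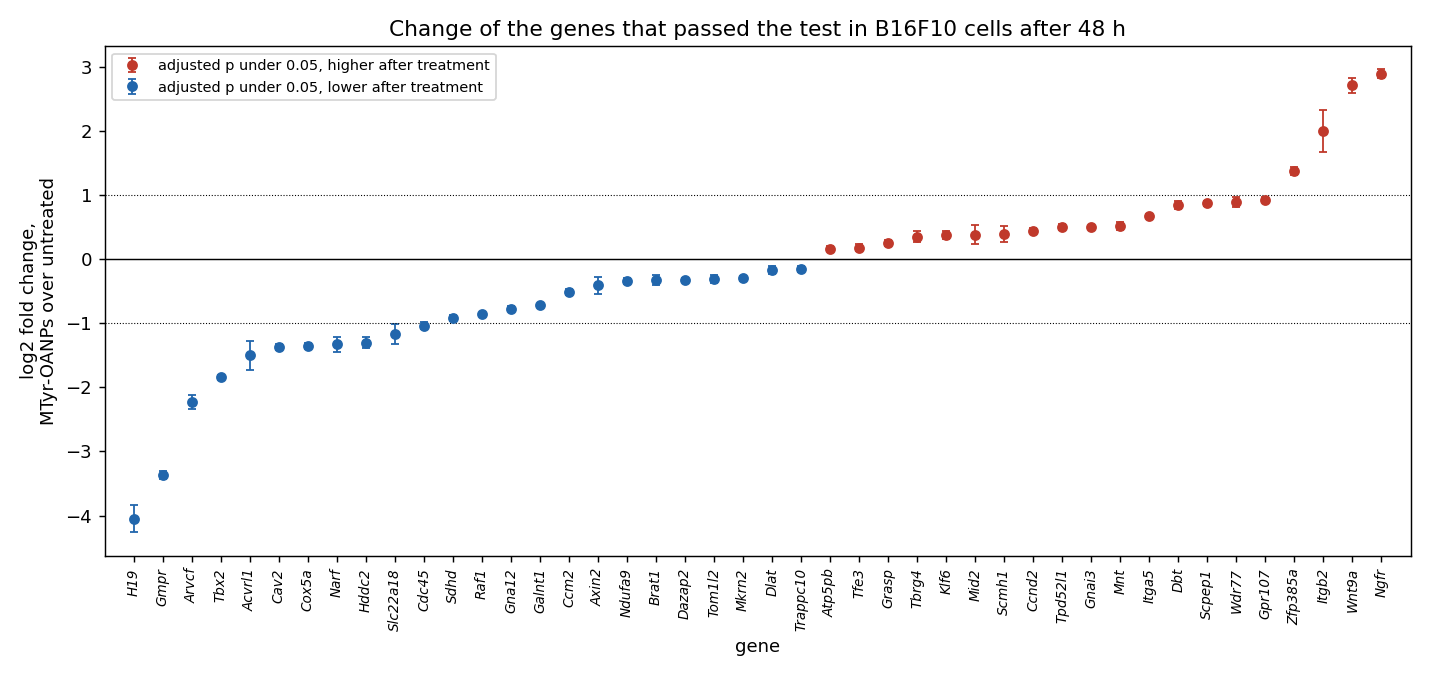
Log2 fold change (MTyr-OANPs over untreated, edgeR) of each of the 44 genes that passed the test, ordered by value, with bars for the standard error from 3 libraries per group and dotted lines at a 2-fold change. Red points are the 20 genes that rose and blue points the 24 that fell; H19 stands lowest at -4.05 and Ngfr highest at 2.89.

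The 3 tested members of the oxidative phosphorylation list fell. Adjusted over the list alone all 3 also passed, which their small p-values in the main test had already assured. Cox5a, a subunit of cytochrome c oxidase, fell 2.56-fold, from 68.0 ± 3.65 to 26.6 ± 0.320 FPKM (SD, n = 3 each; edgeR adjusted p = 4.2e-18). Sdhd, a membrane subunit of succinate dehydrogenase, fell 1.89-fold, from 186 ± 5.37 to 98.6 ± 4.52 FPKM (SD, n = 3 each; edgeR adjusted p = 7.3e-16). Ndufa9, a subunit of NADH dehydrogenase, fell 1.27-fold, from 99.7 ± 4.69 to 78.6 ± 1.85 FPKM (SD, n = 3 each; edgeR adjusted p = 7.3e-08). The direction of these 3 genes did not pass a test against the other called genes, of which 21 fell and 20 rose (Fisher's exact test, two-sided, p = 0.24, adjusted p = 0.61 over 4 lists). With only 3 called genes, no mix of directions could have brought this p under 0.05, so the test decides nothing. The other lists compared had 1 called gene each and could not have passed either. Camera gave p = 0.065 for the list against the other tested genes, and p = 0.27 with an estimated correlation. Atp5pb, a subunit of ATP synthase outside the list, rose 1.12-fold (edgeR adjusted p = 9.5e-04). It was one of the 3 genes with the highest mean FPKM among the 99. Its FPKM went from 88.5 ± 2.09 to 99.2 ± 4.23 (SD, n = 3 each). Exons of Atp5pb overlap Wdr77 on the opposite strand and its transcripts share sequence with Gm12231, so its small rise may include reads of these genes. The call for Atp5pb was lost under quantile normalization (limma adjusted p = 0.22), with a log2 fold change of 0.15 against 0.16; it was 0.30 under TMM and 0.29 with library medians aligned.

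**Figure D2:**
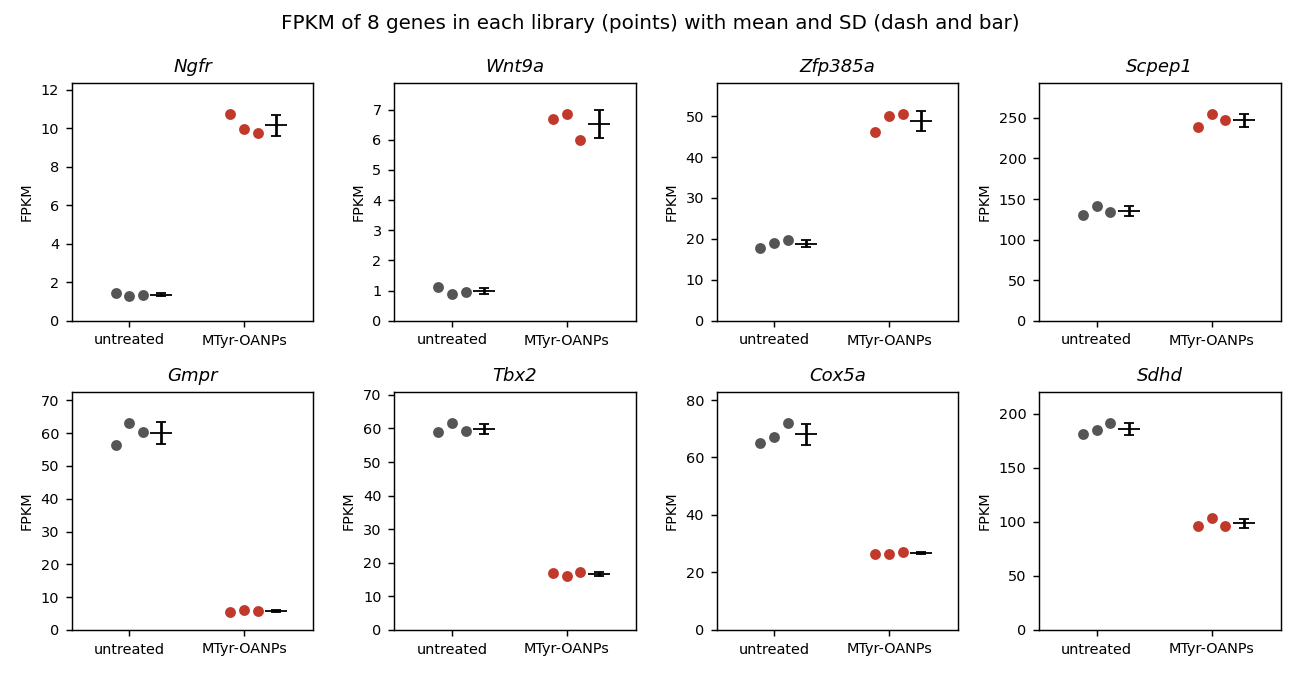
FPKM (linear axis from 0) of 8 genes in each of the 3 untreated libraries (grey points) and the 3 MTyr-OANPs libraries (red points), with the mean as a dash and the SD as a bar. Ngfr, Wnt9a, Zfp385a and Scpep1 are higher and Gmpr, Tbx2, Cox5a and Sdhd lower in each treated library than in any untreated library.

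The other lists had at most 1 tested gene each. Cdc45, part of the replicative helicase and the tested gene of the DNA replication list, fell 2.05-fold, from 25.5 ± 0.447 to 12.4 ± 0.873 FPKM (SD, n = 3 each; edgeR adjusted p = 1.7e-14). Ngfr was the tested gene of the invasive and dedifferentiated melanoma list; Cdh1 of that list stayed below the minimum, with mean counts of 5.3 untreated and 10.7 treated. Tfe3, a transcription factor of lysosomal genes and the tested gene of the lysosome and autophagy list, rose 1.13-fold, from 6.30 ± 0.215 to 7.12 ± 0.411 FPKM (SD, n = 3 each; edgeR adjusted p = 8.1e-03). The call for Tfe3 (log2 fold change 0.18) was lost without untreated library 2 (0.15, edgeR adjusted p = 0.055) and without treated library 3 (0.13, edgeR adjusted p = 0.092). With the trend of length and GC content removed, the change of Tfe3 itself was lost (0.02, edgeR adjusted p = 0.69), while it was larger with library medians aligned (0.30), under TMM (0.32) and under quantile normalization (0.34). Cdc45, Ngfr and Tfe3 were each the only tested gene of their list. Adjustment over the list alone therefore leaves their p-values unadjusted and adds no support.

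Some list genes were below the FPKM minimum of the main test. The tyrosine hydroxylase gene Th had mean counts of 1.3 untreated and 4.0 treated. The interferon-induced gene Mx1 had mean counts of 39.3 untreated and 9.3 treated. The fibroblast marker Fap had a count of 15 in untreated library 3 and was listed at 0 in the other libraries of both groups. In edgeR with no FPKM minimum none of these genes passed, with adjusted p = 0.59 for Th, 0.12 for Mx1 and 0.16 for Fap. Of the 3 KEGG terms with at least 5 tested genes, none passed camera at an unadjusted p under 0.05 (smallest p = 0.27, adjusted p = 0.62; adjusted p = 0.74 with an estimated correlation).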

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

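The alternatives on table totals, DESeq2 with implied depths, counts divided by 4, and the length and GC trend were chosen after the data were seen. TMM, the plan's default, and limma on log2(FPKM + 1), planned for FPKM alone, became alternatives at that point. Over the 22 alternatives, 35 to 51 genes passed the test against 44, with 42 genes tested at the lower end and 83 at the upper. With the same 53 genes tested, 39 to 46 passed, and 40 to 44 did when 1 library was left out. TMM and the shift of library medians raised all log2 fold changes by 0.14 and 0.12; TMM kept 40 of the 44 calls and lost Axin2, Brat1, Dlat and Trappc10. Quantile normalization kept 37 and turned the sign of 1. Calls lost when 1 library was left out were of Tfe3, Axin2, Dlat, Mid2, Trappc10 and Grasp. Genes that rose at least 2-fold numbered 7 with no FPKM minimum (more genes tested), 2 with a minimum of 5 (fewer tested) and 7 under TMM, against 4, and 3 to 6 in the other alternatives; the cause under TMM is its upward shift. Of 589 values of the 27 named genes that passed the test, 585 kept their direction and the call and 4 lost the call (Tfe3 in 3, Atp5pb in 1). Sizes moved more than calls: on log2(FPKM + 1), the log2 fold change of H19 was -1.54 against -4.05 and that of Itgb2 0.90 against 2.00, since the pseudocount shrinks low genes, and under TMM that of Ndufa9 was -0.21 against -0.34. The camera p of the oxidative phosphorylation list, 0.065, was 0.029 with no FPKM minimum, 0.045 with DESeq2 and implied depths, 0.045 with quantile normalization, and 0.051 to 0.094 when 1 library was left out; fry, which tests only whether the 3 genes move one way, gave 3.1e-05. The cause was not tested. Its Fisher p stayed between 0.099 and 0.24, a test that 3 called genes could not have passed. Pairing by number was checked on deviations of log2(FPKM + 1) from the mean of each group. These deviations correlated at 0.31, 0.4 and -0.01 between same-numbered libraries, and at -0.4 to 0.13 between differently numbered ones. Deviations cancel out within a group, so these correlations are not independent and pairing by number stays open. The replicate block gave 45 calls. The melanogenesis list had no gene among the 99, so no alternative was run for it. In simulated tables of this depth 73% of 1.2-fold changes were recovered, so smaller changes can be missed.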

Other observations

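The genes below the FPKM minimum were chosen for description after their values were seen. They are those that passed in the edgeR fit with no FPKM minimum, out of 30 such genes with a count above 0. The tests on splits, scaling, the length and GC trend, gene position and neighbouring genes were also chosen after the results were seen; the test on counts divided by 4 was chosen after the low counts were seen, but before its own result. Tspan32, a tetraspanin of blood cells, fell 12.2-fold, from 1.21 ± 0.265 to 0.0991 ± 0.0505 FPKM (SD, n = 3 each; edgeR adjusted p = 1.6e-40 with no FPKM minimum). Lck, a T cell kinase of the Src family, rose 4.42-fold, from a mean FPKM of 0.291 to 1.29 (mean counts of 69.0 and 300.0, edgeR adjusted p = 3.6e-13). Cttnbp2, which binds cortactin, rose 4.48-fold, from a mean FPKM of 0.135 to 0.605 (mean counts of 95.7 and 425.3, edgeR adjusted p = 4.2e-18). Scml2, of the Polycomb group, fell 2.52-fold (edgeR adjusted p = 9.9e-10), and Trim25, a ubiquitin ligase, fell 2.39-fold (edgeR adjusted p = 2.5e-05). Pdgfb, a platelet-derived growth factor chain, fell 1.47-fold (edgeR adjusted p = 0.019). Gpa33 also passed (edgeR adjusted p = 2.9e-03), with a count of 0 in all untreated libraries and counts of 37, 42 and 0 in treated libraries 1, 2 and 3, so its groups overlap. All these adjusted p-values come from the edgeR fit with no FPKM minimum, which gives far smaller values for strongly changed genes. H19 had an edgeR adjusted p of 7.5e-36 in that fit against 3.1e-13 in the main test, so values of the 2 fits are not comparable.

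Most of the tested genes differed between the groups, 44 of 53. Scaling between libraries does not account for this as a whole: 20 genes rose while 24 fell in the same libraries, and 41 calls were left under TMM. Removing the trend of exonic length and GC content left 46 calls, so such a trend does not account for it either. Dividing the counts by 4 left 45 calls but moved the log2 fold changes of called genes by a median of 0.00085, so it decides nothing about counting in steps of 4. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split gave 44 calls and the highest other split 0. A response to the treatment may account for the changes, as a hypothesis found in the same data. The only controls were untreated cells and the labels give no vehicle group or batch, so handling or batch cannot be told apart from MTyr-OANPs.

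H19, Tspan32 and Slc22a18, which lie within 1 Mb on distal chromosome 7, all fell, by 17.3-fold, 12.2-fold and 2.25-fold. Among 6 clusters of at least 3 genes within 1 Mb, 1 of which lies inside another, drawn from 61 genes with a mean count of at least 50, theirs had the largest mean change, 2.94 on the log2 scale. A mean as large was reached in a share of 0.0023 of 100000 permutations of genes, but the window, the minimum of 3 genes and the count minimum were set after the fall of these genes was seen, so chance among genes stays open. A change in copy number that lowers all 3 genes by the same factor is argued against. The log2 fold changes of Slc22a18 and H19 differ by 2.95 (SE 0.26). A shared factor need not hold where the copies of a gene are expressed unequally, so other changes in copy number stay open. H19 and Slc22a18 are known imprinted genes, and a shared regulation of this region may be involved; that was not tested, and the hypothesis comes from the same data.

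Neighbouring genes might change alike elsewhere too. In 19 pairs of genes within 200 kb, log2 fold changes differed by 1.07 on average, against 1.4 in permuted genes, and a share of 0.11 of permutations gave as small a difference. With 19 pairs, some of them sharing a gene, this leaves the question open.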
